A study of Homo sapiens with 12 samples.

How the data were processed

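The samples were 12 total RNA preparations of the BBe line of Caco-2, a human colon tumour cell line, at day 2, day 8 and day 15 of culture, with 4 replicates each, measured on oligonucleotide arrays of 12625 probe sets. The deposited intensities had been scaled between arrays by the authors, since the 2%-trimmed mean of each array lay between 1000.9 and 1001.01. They were linear and background-subtracted, from -11965 to 197012, with 23.4% of all values at or below 0. The labels do not state the algorithm or software. No column of values per sample was left unused. All arrays were on 1 scale, so no further scaling was applied.

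Values were raised to a floor and put on the log2 scale. The planned floor, the pooled 20th percentile of all values, was -31 and has no logarithm, so the pooled 40th percentile (161), listed beforehand as another choice, was used. The 8210 probe sets above the floor on at least 4 of the 12 arrays were tested, and 4348 dim ones and 67 control probe sets were left out. Gene symbols came from the array's probe table and a RefSeq gene table. Of the probe sets, 10943 had 1 symbol, 545 several and 1070 none, and 9 of the 10943 kept the probe table's symbol because their gene identifier was not in the RefSeq table. A gene was given by its single-gene probe set with the highest mean, which left 5906 tested genes. These genes had 1321 other tested probe sets, each paired with the brightest one of its gene. The brightest passed in 391 pairs for day 8 against day 2, in 200 for day 15 against day 8 and in 573 for day 15 against day 2. Both passed in 165 of these (1 opposite in sign), 77 and 288 (11 opposite in sign). In the rest of these pairs the other probe set did not pass.

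The 3 comparisons were contrasts of group means in 1 linear model of all 12 arrays (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend, 9 residual degrees of freedom, prior df 4.92). P-values were two-sided and adjusted by Benjamini-Hochberg per comparison, with a threshold of 0.05. An F test from the same fit covered the 3 times. Lists of genes written before the data were examined were tested with camera at its preset correlation of 0.01, adjusted over 36 lists and 3 comparisons, and again with an estimated correlation and with fry. Of the 36 lists, 19 were called for day 8 against day 2, 11 for day 15 against day 8 and 18 for day 15 against day 2, and 15, 5 and 14 of these also with an estimated correlation. Probe sets were grouped by their calls in both steps of the time course, with the overlap expected of independent lists, simulated groups without change and the shared arrays split.

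Genes were named by a rule set at the same time as the lists. It took the 6 largest rises and the 6 largest falls per comparison among passing genes whose groups did not overlap, the members of each described list with the smallest adjusted p (up to 4, of which the text gives 1 to 4), any member that passed against its list's majority, and a fixed panel of markers. Members of gene families that the probes may not tell apart were named as uncertain.

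The fit was tested on simulated data made from the arrays. Of changes of 1.5-, 2- and 4-fold put into unchanged groups, it recovered 23.9%, 59.7% and 78.8% for day 8 against day 2, with no call in the wrong direction and 8.87% of the calls false. The changes were put into 67, 67 and 66 probe sets, with noise drawn independently for each probe set. In the data 24.4% of probe sets passed in that comparison, so these shares may not carry over. The alternatives covered the scaling of the arrays, the floor, the filter on dim probe sets, the variance model, the arrays in the fit, a block for replicate number and other probe sets. Others were added after the data were seen, namely a higher floor, a pseudocount, an inverse hyperbolic sine, the actin ratio as a covariate, and the fit without the 2 arrays with the dimmest spike-in controls. For the counts over both steps, all alternatives were added after the data were seen. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.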

Results

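The series followed the BBe line of Caco-2, a human colon tumour cell line whose cells polarise and form a brush border of microvilli once the cultures are crowded. Total RNA was measured at day 2, when the cultures were 50% confluent, at day 8, 4 days after confluence, and at day 15, 11 days after confluence. Each time had 4 replicates, each on an oligonucleotide array of 12625 probe sets. The labels do not say whether the replicates of a time came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The deposited intensities were on 1 scale, with a 2%-trimmed mean of about 1001 on each array. Between 7412 and 7691 probe sets per array lay above the floor of 161 used on the log scale. The number of arrays limits the precision, and the median standard error of a log2 change was 0.24. Levels are means of the deposited intensities ± SD (n = 4), and changes are log2 differences ± SE with p-values from limma, adjusted over the 8210 tested probe sets. A gene is given by its brightest probe set, and a gene at the floor on all 4 arrays of the dimmer time is given as "at least" a fold. Such a gene may have changed more, so its place among the largest changes is not known. The fold of a gene above the floor on 1 to 3 arrays of the dimmer time depends on the floor.

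The arrays grouped by time of culture. Across probe sets, which are not independent replicates, the log2 values of 2 arrays of the same time correlated with Pearson's r of 0.928 to 0.968, and those of arrays of different times with 0.854 to 0.939. No pair of arrays was alike enough to be 1 hybridisation deposited again, since the lowest median absolute log2 difference within a time was 0.18. The ratio of the 3' to the 5' control probe set of actin was 1.10 ± 0.0546 at day 2, 1.44 ± 0.149 at day 8 and 1.59 ± 0.106 at day 15. Each later time differed from day 2 with a two-sided exact permutation p of 0.0286, the smallest that 4 arrays against 4 can give, and an adjusted p of 0.0735 over 18 array measures and comparisons. The same ratio for GAPDH was 1.33 ± 0.104, 1.37 ± 0.122 and 1.41 ± 0.175 (exact p = 0.571 and 0.429 against day 2). The median intensity and the share of probe sets at or below the floor differed from day 2 at both later times with the same exact and adjusted p. The median intensity of an array was 292.5 ± 8.7, 319.5 ± 8.23 and 324.5 ± 1.73 at the 3 times. At or below the floor lay 41.0%, 39.9% and 39.3% of probe sets. The brightest 100 probe sets held 24.2% of the signal at day 2 and 30.3% at day 15, again with that p.

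**Figure D1:**
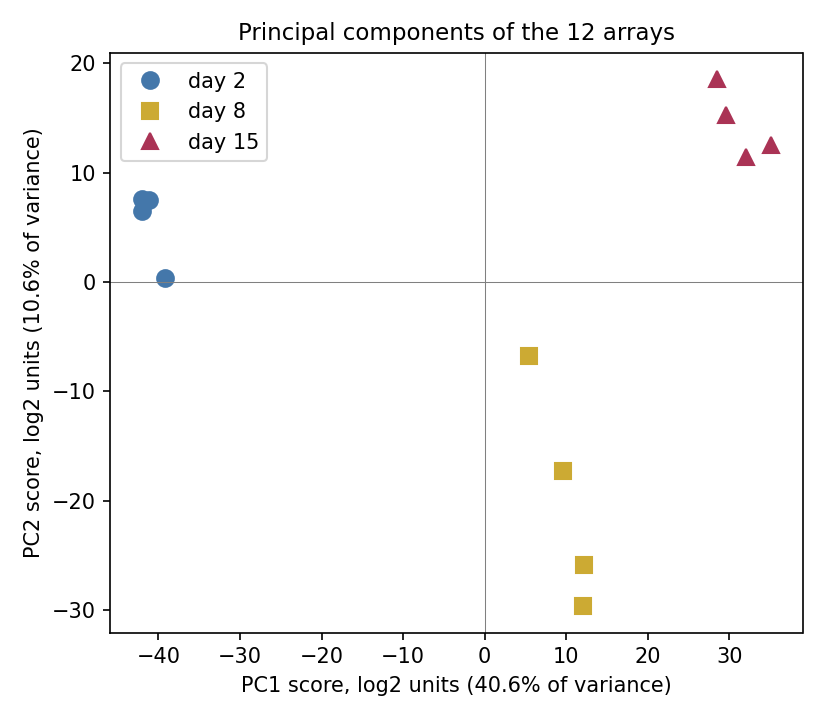
Scores of the 12 arrays on the first and second principal components of the log2 intensities of the tested probe sets, in log2 units, with 1 symbol per array and 1 colour and shape per time (day 2, day 8 and day 15). The first component held 40.6% of the variance and ordered the arrays by day of culture, and the second held 10.6%.

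The comparison of day 8 with day 2 covers the passage from growing cultures to 4 days after confluence. Most of the tested genes of the liver (17 of 24), of lipid handling (10 of 14), of goblet cells (7 of 11) and of the microvillus (8 of 13, with 3 that fell) rose. Most of the mitosis (43 of 52), ribosome biogenesis (16 of 23) and heat shock genes (15 of 22) fell. The largest rise was that of ALB, which encodes serum albumin, from 278 ± 159 to 9603 ± 722 (SD, n = 4), a 35.7-fold change (log2 change 5.16 ± 0.26, adjusted p = 4.23e-09). MYO1A, the myosin that ties the actin core of a microvillus to its membrane, went from 426 ± 39.8 to 4037 ± 257 (9.48-fold, adjusted p = 5.26e-11). The largest fall was that of NPPB, which encodes the B-type natriuretic peptide precursor, from 4741 ± 250 to the floor on all 4 day 8 arrays, at least 29.4-fold lower (log2 change -4.88 ± 0.20, adjusted p = 3.75e-10).

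Next to ALB, the largest rises were those of ITIH2 (17.6-fold), a heavy chain of a plasma protease inhibitor, AFP (16.8-fold), the fetal serum protein alpha-fetoprotein, MSMB (14.7-fold), which encodes a secreted protein of mucosal tissues, CFB, complement factor B (at least 14-fold), and TFF1, a trefoil peptide of mucus (11.4-fold). Each had an adjusted p of 9.02e-08 or lower. Of the falls, NPPB was joined by GAL, which encodes the neuropeptide galanin (16.5-fold), TAGLN, an actin-binding protein of contractile cells (9.09-fold), OLR1, a receptor for oxidised lipoprotein (8.76-fold), RAC3, a small GTPase (6.57-fold), and CCN1, a secreted matrix protein of early growth responses (at least 6.33-fold). After NPPB, the adjusted p-values were between 3.64e-08 for TAGLN and 5.99e-05 for RAC3. In each of these genes all 4 values of one time lay above all 4 of the other.

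Among the lists fixed before the data were examined, the liver secretory and fetal genes had 24 tested members, of which 17 rose and 7 did not pass (17 rose adjusted over the list alone), with a camera adjusted p of 9.29e-18. Of the liver genes 32 were on the array, and AMBP, SERPINC1 and TF, named after their values were seen, were among those too dim to test. SERPINA1, alpha-1-antitrypsin, reached 26480 ± 1994 from 4976 ± 363 (5.32-fold), the fibrinogen chain FGB 19247 ± 809 from 2782 ± 390 (6.97-fold), and the fetuin AHSG 22934 ± 2442 from 3552 ± 267 (6.44-fold). The lipid absorption and lipoprotein genes rose in 10 of 14 tested members (11 adjusted over the list alone, camera adjusted p = 8.87e-11). Of the lipid genes 19 were on the array, and APOA4, MTTP, FABP2, CD36 and LCAT, named after their values were seen, were too dim to test. FABP1, the fatty acid binding protein of liver and intestine, rose 5.01-fold to 15175 ± 2017, APOC3 4.29-fold to 42916 ± 5319 and APOB 2.89-fold to 7636 ± 989. Of the brush border hydrolases 17 were on the array and 7 bright enough to test, of which 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0113). Without the filter on dim probe sets the mean log2 change of the list went from 1.04 to 0.44 and its call ended (adjusted p = 0.0882). MEP1A, a meprin protease subunit, rose 9.59-fold and the dipeptidase DPP4 2.22-fold to 5177 ± 543, while ANPEP, aminopeptidase N, rose at least 2.47-fold (adjusted p = 0.00201). SI, sucrase-isomaltase, had 31 ± 35.8 at day 2 and 208 ± 176 at day 8 and did not pass (adjusted p = 0.228). The actin ratio given above was also higher on the day 8 arrays. With it as a covariate the calls of the liver, lipid and brush border lists held.

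The microvillus cytoskeleton and scaffold list rose in 8 and fell in 3 of 13 tested members (9 and 3 adjusted over the list alone, camera adjusted p = 0.0107). The capping protein EPS8 rose 2.68-fold and the bundling protein VIL1, villin, 1.54-fold to 5093 ± 280. The 3 that fell were FSCN1, the filopodial bundling protein fascin (3.37-fold), CNN3, a calponin (2.42-fold), and PLS3, T-plastin (1.36-fold, adjusted p = 0.0440). The call of PLS3 ended with the actin ratio as a covariate (log2 change 0.06, adjusted p = 0.911) and in 12 other alternatives, among them the fits without day 2 replicate 2, 3 or 4, day 8 replicate 1, 3 or 4, or day 15 replicate 1 or 2 (adjusted p between 0.0538 and 0.141). Intestinal transporters rose in 7 and fell in 2 of 18 tested members (9 and 3 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.0873 with an estimated correlation). Of the transporter genes 24 were on the array, and SLC5A1, SLC2A2, SLC10A2 and SLC9A3, named after their values were seen, were among those too dim to test. The water and glycerol channel AQP3 rose 2.93-fold to 6491 ± 1211 and the ferroxidase HEPH 2.57-fold, while the amino acid transporter chain SLC3A2 fell 1.49-fold and the folate carrier SLC19A1 1.55-fold. Intestinal transcription factors rose in 10 and fell in 1 of 21 tested members (10 and 1 adjusted over the list alone, camera adjusted p = 0.000506). KLF5 rose 3.88-fold and NR1H3, the liver X receptor alpha, 3.12-fold, and FOXA2 fell 2.76-fold (adjusted p = 0.0109). The call of FOXA2 was lost on its other probe set (log2 change -0.40, adjusted p = 0.325) and with the actin ratio as a covariate (adjusted p = 0.817). Drug metabolism and efflux genes rose in 12 and fell in 2 of 31 tested members (13 and 3 adjusted over the list alone, camera adjusted p = 0.00277). ABCC3, an efflux pump, rose 3.78-fold, the retinal dehydrogenase ALDH1A1 2.55-fold, and SULT1A1, whose probe set can detect near-identical sulfotransferases and is uncertain, 2.87-fold. CYP1A1, a monooxygenase of the aryl hydrocarbon response, fell 4.47-fold from 4606 ± 1195 to 1012 ± 116, and the mitochondrial dehydrogenase ALDH1B1 fell at least 1.88-fold.

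Lists of goblet cell, colonocyte and Paneth cell genes rose together, among the members bright enough to test. The goblet cell genes SPDEF, CLCA1 and SPINK4 and the Paneth cell genes DEFA5, DEFA6, REG3A and MMP7 lay above the floor on too few arrays to be tested. These were named after their values were seen. Enteroendocrine genes rose in 1 of 8 tested members (camera adjusted p = 0.663). Of the goblet cell genes 7 of 11 tested members rose (7 adjusted over the list alone, camera adjusted p = 1.13e-05), among them the trefoil peptides TFF3 (5.87-fold, to 15496 ± 1241; log2 change 2.55, but 0.91 on 1 of its other probe sets) and TFF2 (5.80-fold). Of the colonocyte genes 9 of 20 rose (10 adjusted over the list alone, camera adjusted p = 9.46e-07), with the adhesion molecule CEACAM5 up 7.87-fold, CEACAM6 3.72-fold and the tetraspanin TSPAN8 2.57-fold. Of the Paneth cell genes 4 of 7 rose (4 adjusted over the list alone, camera adjusted p = 0.000907), namely the secreted phospholipase PLA2G2A (6.54-fold), PRSS2 (3.49-fold), a trypsinogen whose relatives the probe set can detect, the trypsin inhibitor SPINK1 (2.44-fold) and lysozyme, LYZ (2.54-fold). Antigen presentation and interferon genes rose in 7 of 24 tested members (7 adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.141 with an estimated correlation), IRF9 1.81-fold and HLA-E, uncertain among its relatives, 2.31-fold. Gluconeogenesis genes rose in 3 of 5 (3 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.159 with an estimated correlation), FBP1, fructose bisphosphatase, by 2.49-fold from around the floor, a call that ended with the higher floor (log2 change 0.02, adjusted p = 0.909).

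Of 52 tested mitosis genes 43 fell and 9 did not pass (47 adjusted over the list alone, camera adjusted p = 3.96e-23). FOXM1, a transcription factor of the G2 phase, fell 2.46-fold from 7020 ± 154 to 2852 ± 40.5, MYBL2 2.52-fold and the ubiquitin carrier UBE2S 2.85-fold. DNA replication genes fell in 19 of 42 tested members (23 adjusted over the list alone, camera adjusted p = 3.55e-10), thymidine kinase TK1 2.04-fold and the sliding clamp PCNA 1.79-fold. Ribosome biogenesis genes fell in 16 of 23 (16 adjusted over the list alone, camera adjusted p = 2.27e-08), nucleolin, NCL, by 1.57-fold and RRP1B by 1.97-fold. The cytosolic ribosomal proteins themselves rose in 21 of 46 (23 adjusted over the list alone, camera adjusted p = 5.34e-07, adjusted p = 0.430 with an estimated correlation), RPL22 by 1.63-fold. Cytosolic heat shock proteins fell in 15 of 22 (16 adjusted over the list alone, camera adjusted p = 8.44e-08), the chaperonin subunits CCT7 and CCT2 by 1.57-fold each, and proteasome genes in 14 of 30 (17 adjusted over the list alone, camera adjusted p = 2.81e-05), PSMD11 by 1.46-fold. Polyamine and one-carbon genes fell in 13 and rose in 4 of 25 (14 and 4 adjusted over the list alone, camera adjusted p = 0.0161). Ornithine decarboxylase, ODC1, fell 1.93-fold from 19330 ± 1526 to 9985 ± 641, and spermidine synthase, SRM, 2.41-fold, a direction that its dimmer probe set did not share (log2 change 0.19, adjusted p = 0.647). The 4 that rose were the urea cycle enzymes ASS1 (2.26-fold) and ASL (2.81-fold), ornithine aminotransferase OAT (2.01-fold) and the polyamine acetyltransferase SAT1 (1.62-fold).

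In all, 2003 probe sets changed, 1069 of them upward (53.4%), and 669 by at least 2-fold. The 4 values of one time all lay above the 4 of the other in 26.8% of tested probe sets, against 2.86% by chance. Dividing each array by its own median moved the median log2 change of all probe sets from 0.06 to -0.05 and the upward share to 38% (790 of 2080). With the actin ratio as a covariate, a choice made after seeing the data, 853 probe sets passed and the ribosomal protein list shifted down (camera adjusted p = 0.0474). Under it the antigen and gluconeogenesis lists no longer passed (adjusted p = 0.343 and 0.152), with mean log2 changes of 0.325 and 0.591 against 0.406 and 0.642 in the main fit. The log2 change of PLS3 under it was 0.06. Of 125 calls of named genes 31 ended, among them those of ANPEP, CNN3, SLC19A1, ALDH1B1, LYZ, HLA-E, IRF9 and FBP1 (adjusted p from 0.0557 for CNN3 to 0.371 for ANPEP). The call of GAL ended without a floor (adjusted p = 0.0503). That of PCNA ended on another probe set, although the fall there was larger (log2 change -1.53, adjusted p = 0.0594). Here ALB, MSMB, GAL, OLR1, FOXA2, FBP1 and TFF2 lay above the floor on 1 to 3 arrays of the dimmer time. Leaving out 1 array also ended the call of the antigen list (day 2 replicate 2 or 3, or day 8 replicate 1, 2 or 4, adjusted p between 0.0520 and 0.107) and of the gluconeogenesis list (day 8 replicate 1 or 4, or day 15 replicate 4, adjusted p between 0.0527 and 0.0809).

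The comparison of day 15 with day 8 follows the cultures from 4 to 11 days after confluence, and fewer genes changed. Some of the transporter (5 of 18), ribosomal protein (19 of 46) and respiratory chain genes (11 of 53) rose, and some of the heat shock (12 of 22), immediate early (6 of 23) and Wnt-related genes (6 of 22) fell. The transporter and ribosomal protein lists did not pass with an estimated correlation (adjusted p = 0.0829 and 0.199). SI, sucrase-isomaltase, the disaccharidase of the small intestinal brush border, went from 208 ± 176 to 656 ± 127 (SD, n = 4; 2.75-fold, log2 change 1.46 ± 0.30, adjusted p = 0.00598). At day 8 it lay above the floor on 2 of 4 arrays, so the fold depends on the floor, and without a floor the change did not pass (adjusted p = 0.335, the highest of its alternatives). CDX2, an intestinal homeobox factor, rose 1.57-fold from 3764 ± 606 to 5850 ± 459 (adjusted p = 0.00169). DKK1, a secreted Wnt inhibitor and Wnt target, fell 5.45-fold from 4583 ± 580 to 871 ± 308 (log2 change -2.45 ± 0.18, adjusted p = 1e-06).

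The largest rise was that of CD68, a lysosomal protein of macrophages and other cells, from 561 ± 521 to 2801 ± 461 (6.12-fold, adjusted p = 0.00194). It was followed by GUCA2A, the intestinal peptide guanylin (5.82-fold), SULT2A1, a steroid sulfotransferase (5.44-fold), CHAF1B, a subunit of a histone chaperone of DNA replication (5.09-fold), RBMXL2 (at least 4.73-fold) and GLB1L2 (4.30-fold). Their adjusted p-values were between 3.13e-05 for SULT2A1 and 0.00577 for GLB1L2. Without a floor CD68, GUCA2A, SULT2A1 and CHAF1B did not pass (adjusted p = 0.0699, 0.0996, 0.282 and 0.185), and GLB1L2 did not on its other probe set (log2 change 0.59, adjusted p = 0.254). The largest falls were those of TPTEP1, a transcribed pseudogene (8.70-fold, adjusted p = 1.57e-05), GAMT, which makes creatine (7.11-fold, adjusted p = 0.00137), the collagenase MMP1 (6.76-fold, adjusted p = 4.63e-06), the phosphatase DUSP5 (6.50-fold, adjusted p = 4.63e-06), the growth factor receptor PDGFRB (6.01-fold, adjusted p = 0.00143, and 0.226 without a floor) and DKK1.

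Cytosolic ribosomal proteins rose in 19 of 46 tested members (32 adjusted over the list alone, camera adjusted p = 1.14e-15, adjusted p = 0.199 with an estimated correlation), RPL22 by 1.60-fold and RPL30 by 1.51-fold. Oxidative phosphorylation genes rose in 11 of 53 (15 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.79e-06). ATP5MC1, a subunit of ATP synthase, rose 1.47-fold to 15230 ± 1828 and NDUFB5, of complex I, 1.32-fold. Intestinal transporters rose in 5 and fell in 1 of 18 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.0829 with an estimated correlation). The iron transporter SLC11A2 rose 2.37-fold to 6005 ± 385, the chloride and bicarbonate exchanger SLC26A3 4.15-fold to 1216 ± 94.5 (adjusted p = 0.356 without a floor) and the amino acid transporter chain SLC7A7 1.41-fold, and the chloride channel CFTR fell 1.62-fold.

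Cytosolic heat shock proteins fell in 12 of 22 tested members (12 adjusted over the list alone, camera adjusted p = 1.45e-09), the small heat shock protein HSPB1 2.94-fold from 4290 ± 812 to 1480 ± 386. Immediate early genes fell in 6 of 23 (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000814), IER3 5.19-fold from 3262 ± 233 to 632 ± 86.8 and FOS 2.51-fold. Wnt targets and crypt genes fell in 6 and rose in 1 of 22 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0136). ID1, an inhibitor of DNA binding, fell 2.59-fold and SOX4 1.90-fold, and ASCL2, a stem cell factor of the crypt, rose 2.41-fold (adjusted p = 0.0408), a call that ended in 15 alternatives (adjusted p up to 0.213). DNA replication genes fell in 7 and rose in 1 of 42 (8 and 3 adjusted over the list alone, camera adjusted p = 0.00766), PCNA by 1.52-fold (log2 change -1.36 and adjusted p = 0.144 on another probe set), and CHAF1B was the one that rose. Ribosome biogenesis genes fell in 5 and rose in 1 of 23 (6 and 2 adjusted over the list alone, camera adjusted p = 0.00766, adjusted p = 0.0674 with an estimated correlation), the helicase DDX21 falling 2.63-fold and fibrillarin, FBL, rising 1.39-fold. Mitosis genes fell in 6 and rose in 1 of 52 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0417, adjusted p = 0.0517 with an estimated correlation), MKI67 falling 1.45-fold on 1 of its probe sets while the other gave a log2 change of 0.19 (adjusted p = 0.685), and separase, ESPL1, rising 1.57-fold. Fibroblast and matrix genes fell in 3 of 15 (3 adjusted over the list alone, camera adjusted p = 0.0340, adjusted p = 0.0778 with an estimated correlation), namely PDGFRB, fibronectin, FN1 (2.03-fold), and TAGLN (1.77-fold). Proteasome genes fell in 3 of 30 (3 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.124 with an estimated correlation), among them PSMC3 by 1.27-fold. Leaving out 1 array ended the call of ASCL2 (day 2 replicate 1, 3 or 4, day 8 replicate 1, 2 or 3, or day 15 replicate 3 or 4, adjusted p between 0.0509 and 0.115). It ended that of TAGLN without day 15 replicate 4 (adjusted p = 0.0515). That of PSMC3 ended without replicate 1 of day 8 or of day 15 (adjusted p = 0.0533 and 0.0659).

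Some lists that had risen by day 8 were not called between day 8 and day 15. Brush border hydrolases rose in 1, SI, and fell in 1 of 7 tested members (3 and 2 adjusted over the list alone, camera adjusted p = 0.6245), with DPP4 down 1.34-fold to 3863 ± 263 (adjusted p = 0.00529). Microvillus genes fell in 2 of 13 (3 adjusted over the list alone, camera adjusted p = 0.212), namely FSCN1 (3.99-fold) and CNN3 (2.08-fold). Liver secretory and fetal genes rose in 5 and fell in 5 of 24 tested members (5 and 9 adjusted over the list alone), with a mean log2 change of -0.13, a median of 0.00 and a camera adjusted p of 0.440. RBP4, the retinol carrier of plasma, rose 1.30-fold to 11286 ± 750, and ITIH2 fell 2.08-fold to 2789 ± 406. Colonocyte genes rose in 3 and fell in 4 of 20 (4 and 4 adjusted over the list alone, camera adjusted p = 0.860), with CEACAM6 down 3.95-fold and TSPAN8 up 1.36-fold. Goblet cell genes fell in 2 of 11 (2 adjusted over the list alone), namely AGR2, a folding factor of mucins (2.15-fold), and TFF1 (2.04-fold), with a mean log2 change of 0.03, a median of 0.15 and a camera test pointing down (adjusted p = 0.729). Paneth cell genes fell in 3 of 7 (3 adjusted over the list alone, camera adjusted p = 0.104), PLA2G2A 4.41-fold to 2004 ± 466, LYZ 2.30-fold and SPINK1 1.18-fold. The call of LYZ ended without day 8 replicate 1 (adjusted p = 0.0506). That of SPINK1 ended without any 1 array other than replicate 2 of day 2 or of day 8 (adjusted p between 0.0552 and 0.124).

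CD68, GUCA2A, SULT2A1, CHAF1B, GLB1L2, SLC26A3, ASCL2, GAMT and PDGFRB lay above the floor on 1 to 3 arrays of the dimmer time. In all, 929 probe sets changed, 435 upward and 494 downward, and 226 by at least 2-fold. All 4 values of one time lay above the 4 of the other in 15.9% of tested probe sets. Leaving out 1 array ended the call of the mitosis list (day 8 replicate 3 or 4, or day 15 replicate 1, 2 or 4, adjusted p between 0.0517 and 0.0765) and of the fibroblast list (day 8 replicate 2 or day 15 replicate 4, adjusted p = 0.0530 and 0.133). It also ended that of the proteasome list (day 8 replicate 2, 3 or 4, or day 15 replicate 1 or 4, adjusted p between 0.0527 and 0.129). The calls of all 3 ended in other settings too, among them the higher floor for mitosis and proteasome (adjusted p = 0.0788 and 0.0675) and the actin covariate for fibroblast genes (adjusted p = 0.0840).

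The comparison of day 15 with day 2 spans the whole time course. Most of the tested lipid (12 of 14), liver (19 of 24), goblet cell (6 of 11) and brush border genes (5 of 7) were higher at day 15. Most of the mitosis (45 of 52), ribosome biogenesis (17 of 23), heat shock (18 of 22) and proteasome genes (19 of 30) were lower. SI, at the floor on all 4 day 2 arrays (31 ± 35.8), reached 656 ± 127 (SD, n = 4), at least 4.02-fold higher (log2 change 2.01 ± 0.30, adjusted p = 0.000107). MYO1A rose 10.1-fold to 4308 ± 177 (adjusted p = 2.48e-11), and GUCY2C, the intestinal receptor of guanylin, 12.7-fold to 2815 ± 31.8 (adjusted p = 8.09e-08). MKI67, a nuclear marker of cycling cells, fell 2.52-fold from 2684 ± 186 to 1067 ± 69.8 (log2 change -1.33 ± 0.11, adjusted p = 3.36e-07), while its dimmer probe set gave a log2 change of 0.10 (adjusted p = 0.772).

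The largest rises were those of AFP (19.2-fold, from 564 ± 120 to 10631 ± 1037), CD68 (at least 17.2-fold), ALB (15.7-fold), the aldehyde dehydrogenase ALDH3B1 (14.4-fold), kininogen, KNG1 (14-fold), and GUCY2C. The largest falls were those of NPPB (at least 29.4-fold), GAL (23.3-fold), TAGLN (16.1-fold, from 30230 ± 2275 to 1966 ± 671), DKK1 (15.3-fold, from 12771 ± 652 to 871 ± 308), CYP1A1 (14.8-fold) and FSCN1 (13.4-fold). CD68 had an adjusted p of 6.54e-06 and each of the others 8.09e-08 or lower.

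The panel of marker genes always reported had 18 of its 19 genes on the array as single-gene probe sets, HNF4A being the exception. LCT, lactase, APOA4, the glucose transporter SLC5A1 and the vitamin D hydroxylase CYP24A1 lay above the floor on too few arrays to be tested. Of the 14 tested, 7 rose and 4 fell (8 and 4 adjusted over the list alone). SI rose as given above, DPP4 1.66-fold to 3863 ± 263, VIL1 1.48-fold to 4902 ± 222, CDX2 2.24-fold to 5850 ± 459, FABP1 3.79-fold to 11448 ± 1150, APOA1 2.69-fold from 24542 ± 2908 to 65988 ± 6731, and the cell cycle inhibitor CDKN1A at least 3.86-fold to 757 ± 398 (adjusted p = 0.010). MKI67, CCNB1 (2.91-fold), TOP2A (1.38-fold) and MYC (1.34-fold, adjusted p = 0.0253) fell. The call of MYC ended on 1 of its other probe sets (adjusted p = 0.130), while the remaining ones fell and passed (log2 change -0.463 and -0.736, adjusted p = 0.000847 and 0.00141). It also ended without day 2 replicate 1 or 3 or day 15 replicate 1 or 2 (adjusted p between 0.0555 and 0.0807). ALPI, intestinal alkaline phosphatase, went from 544 ± 190 to 616 ± 115 (log2 change 0.22 ± 0.31, adjusted p = 0.614), ANPEP from 43.5 ± 45.1 to 258 ± 65.2 (log2 change 0.64 ± 0.26, adjusted p = 0.0727) and the vitamin D receptor VDR from 275 ± 71.9 to 429 ± 165 (log2 change 0.61 ± 0.34, adjusted p = 0.187), and none of the 3 passed.

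**Figure D2:**
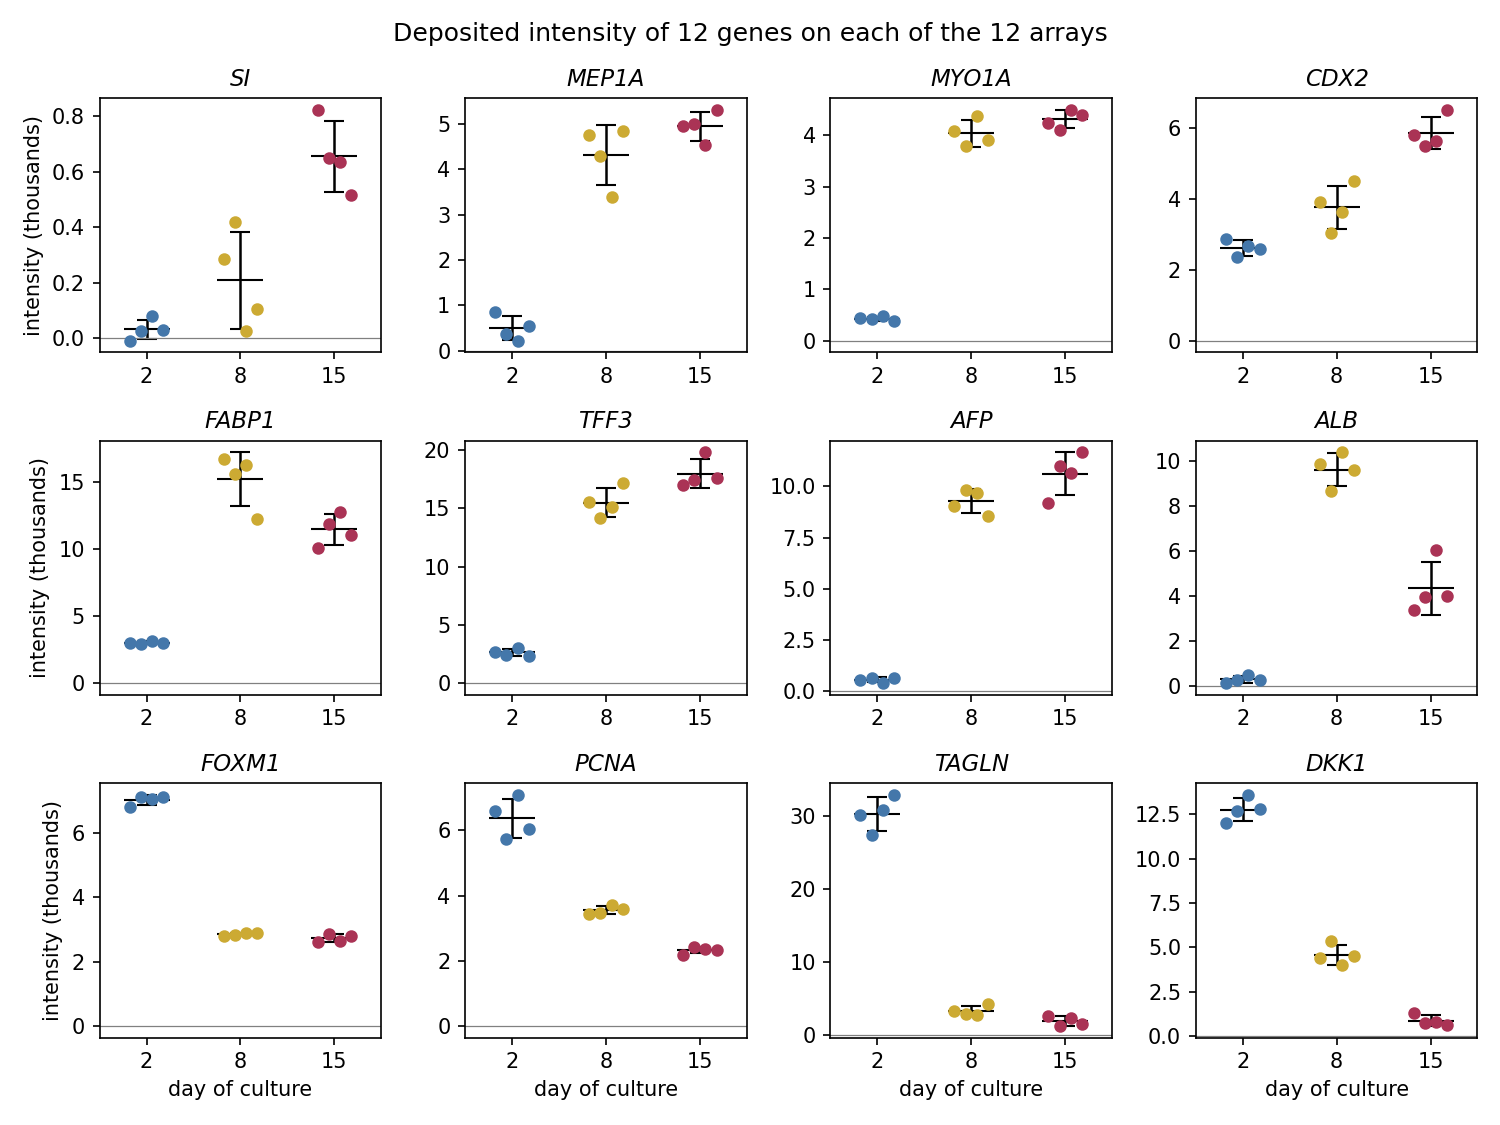
Deposited intensity (in units of 1e3, vertical axis) of 12 genes at day 2, day 8 and day 15 of culture (horizontal axis), with 1 coloured point per array and the mean ± SD of 4 arrays as a black line with bars. SI (656 ± 127), MYO1A and AFP had their highest mean at day 15 and ALB at day 8, and FOXM1, PCNA, TAGLN and DKK1 had theirs at day 2.

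Lipid absorption and lipoprotein genes rose in 12 and fell in 1 of 14 tested members (12 and 1 adjusted over the list alone, camera adjusted p = 2.98e-08). APOB rose 4.26-fold to 11178 ± 421 and DGAT1, which makes triglycerides, 4.04-fold to 16745 ± 776. The one that fell was the cholesterol exporter ABCA1 (2.89-fold, adjusted p = 0.0457), whose other probe set gave a log2 change of 0.09 (adjusted p = 0.868). Its call also ended without any 1 day 2 array, day 8 replicate 3 or 4, or day 15 replicate 2, 3 or 4 (adjusted p between 0.0508 and 0.131). Brush border hydrolases rose in 5 of 7 (6 adjusted over the list alone, camera adjusted p = 0.00766), MEP1A by 11.1-fold. Without the filter on dim probe sets the mean log2 change of the list went from 1.48 to 0.64 and its call ended (adjusted p = 0.0716). Intestinal transporters rose in 8 and fell in 1 of 18 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00639), SLC11A2 by 4.46-fold and AQP3 by 3.10-fold, and SLC19A1 fell 1.45-fold. Intestinal transcription factors rose in 11 and fell in 1 of 21 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000506), with MAF up 10.4-fold to 2063 ± 341 from 172 ± 107, around the floor (log2 change 3.38, and 1.91 with the higher floor), CEBPA up 2.82-fold and HES1, a Notch target, down 1.26-fold. Drug metabolism and efflux genes rose in 14 and fell in 4 of 31 (18 and 4 adjusted over the list alone, camera adjusted p = 0.00766). ABCC3 rose 5.77-fold and ALDH1A1 3.71-fold, and CYP1A1, the glutathione peroxidase GPX2 (2.22-fold), ALDH1B1 (at least 1.88-fold) and the efflux pump ABCC4 (1.87-fold, adjusted p = 0.0562 without a floor) fell. The microvillus list rose in 8 and fell in 3 of 13 (8 and 3 adjusted over the list alone) and its camera test did not pass (adjusted p = 0.133).

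Liver secretory and fetal genes rose in 19 of 24 tested members (19 adjusted over the list alone, camera adjusted p = 3.03e-13), GPC3, the fetal proteoglycan glypican 3, by 3.74-fold from 6688 ± 109 to 25010 ± 338. Goblet cell genes rose in 6 of 11 (7 adjusted over the list alone, camera adjusted p = 0.000908), TFF3 by 6.81-fold to 17968 ± 1254 (log2 change 2.77, but 0.98 on 1 of its other probe sets) and the lectin ZG16 by 4.93-fold. Colonocyte genes rose in 11 of 20 (11 adjusted over the list alone, camera adjusted p = 0.000263), TSPAN1 by 5.46-fold and the ion transport regulator FXYD3 by at least 8.12-fold. Paneth cell genes rose in 2 of 7 (3 adjusted over the list alone, camera adjusted p = 0.0473, adjusted p = 0.109 with an estimated correlation and 0.0542 with a block for replicate number), PRSS2 by 3.80-fold and SPINK1 by 2.06-fold. Gluconeogenesis genes rose in 3 of 5 (3 adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.144 with an estimated correlation), FBP1 by 5.35-fold. Cytosolic ribosomal proteins rose in 40 of 46 (42 adjusted over the list alone, camera adjusted p = 9.08e-14, adjusted p = 0.229 with an estimated correlation), RPL22 by 2.60-fold to 19246 ± 771. Oxidative phosphorylation genes rose in 18 and fell in 4 of 53 (19 and 4 adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.258 with an estimated correlation). NDUFB5 rose 1.85-fold, and NDUFS5, NDUFS6, NDUFC1 and UQCRQ fell by 1.41-, 2.04-, 1.23- and 1.24-fold. The call of UQCRQ ended without day 2 replicate 1 or 3 or day 15 replicate 4 (adjusted p between 0.0538 and 0.0638). The actin ratio was higher at day 15 in step with these groups.

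Mitosis genes fell in 45 and rose in 1 of 52 tested members (46 and 1 adjusted over the list alone, camera adjusted p = 2.32e-18), KPNA2, a nuclear import receptor, by 2.98-fold and FOXM1 by 2.57-fold, and ESPL1 rose 1.36-fold. The call of ESPL1 ended under median scaling (adjusted p = 0.137) and without day 2 replicate 1, 3 or 4 or day 15 replicate 4 (adjusted p between 0.0580 and 0.107). DNA replication genes fell in 28 and rose in 1 of 42 (28 and 1 adjusted over the list alone, camera adjusted p = 3.84e-09), the flap endonuclease FEN1 by 3.40-fold and PCNA by 2.72-fold from 6364 ± 596 to 2334 ± 104, and CHAF1B rose 5.58-fold. Ribosome biogenesis genes fell in 17 of 23 (19 adjusted over the list alone, camera adjusted p = 1.04e-07), DDX21 by 4.25-fold, and cytosolic heat shock proteins in 18 of 22 (18 adjusted over the list alone, camera adjusted p = 8.74e-11), DNAJA1 by 2.63-fold. Proteasome genes fell in 19 of 30 (20 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.95e-06), PSMD11 by 1.81-fold. Polyamine and one-carbon genes fell in 13 and rose in 4 of 25 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00831). ODC1 fell 2.98-fold to 6510 ± 836, and ASS1 (7.04-fold, from 2933 ± 550 to 20370 ± 519), OAT (3.83-fold), ASL (3.27-fold) and the guanine nucleotide enzyme IMPDH2 (1.61-fold) rose.

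**Figure D3:**
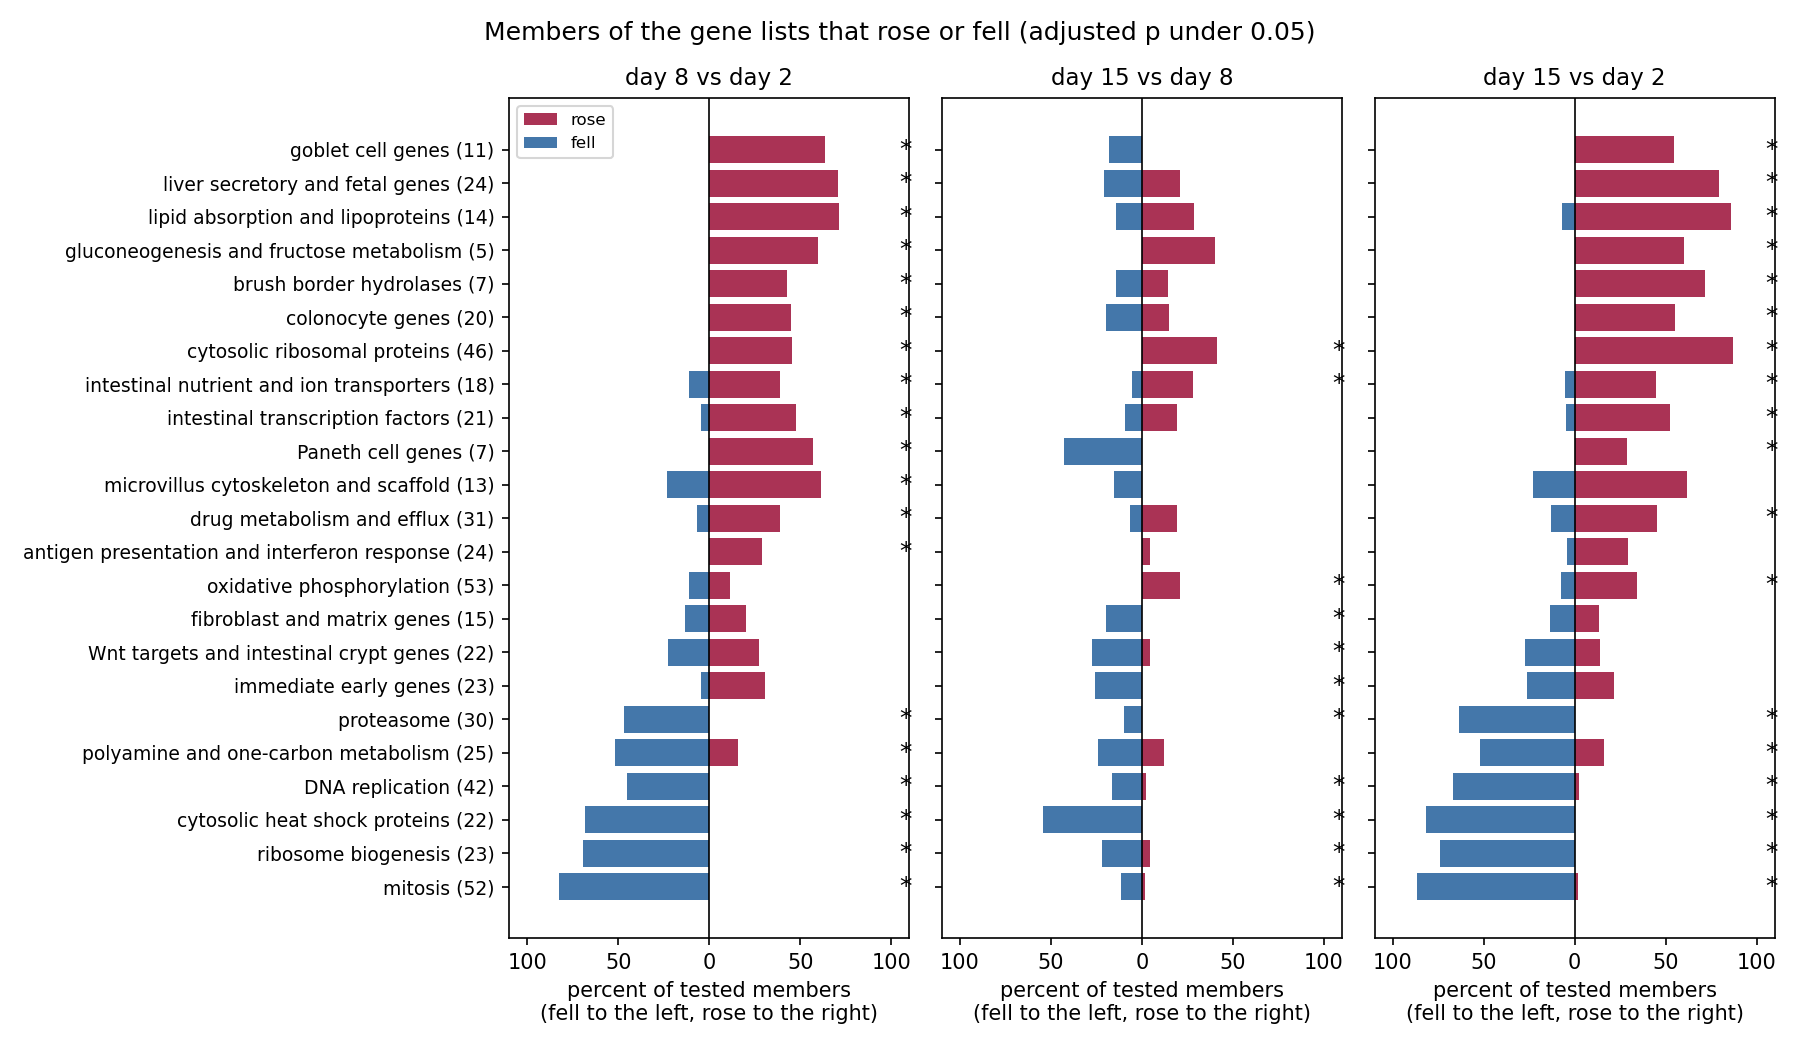
Percent of the tested members (number in brackets) of 23 gene lists that rose (red, right) or fell (blue, left) at adjusted p under 0.05 in each of the 3 comparisons, with an asterisk where the camera test of the list passed after adjustment. The plot shows the lists called in at least 1 comparison: in day 15 against day 2, 40 of 46 ribosomal protein genes rose and 45 of 52 mitosis genes fell.

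In all, 2953 probe sets changed from day 2 to day 15, 1549 upward (52.5%), and 1291 by at least 2-fold. All 4 values of one time lay above the 4 of the other in 36.6% of tested probe sets. Dividing each array by its own median moved the median log2 change of all probe sets from 0.10 to -0.03, the upward share to 39.3% (1135 of 2889) and the camera adjusted p of the oxidative phosphorylation list to 0.273. With the actin ratio as a covariate 946 probe sets passed. The ribosomal protein, oxidative phosphorylation, gluconeogenesis and Paneth cell lists then did not (camera adjusted p = 0.632, 0.945, 0.0903 and 0.114), and the camera test of oxidative phosphorylation pointed down. The mean log2 changes of these lists were then 0.024, 0.068, 0.935 and 0.51, against 0.783, 0.191, 1.01 and 0.649 in the main fit. The log2 changes of CDKN1A and ABCA1 were -0.20 and 0.68 without passing. Of 152 calls of named genes 54 ended, among them those of DPP4, VIL1, CDX2, APOA1, TOP2A and CCNB1 (adjusted p from 0.0509 for VIL1 to 0.598 for CCNB1). ALB, ALDH3B1, GUCY2C, GAL, MAF, FBP1, ZG16, CHAF1B, ABCA1 and ABCC4 lay above the floor on 1 to 3 arrays of the dimmer time. Other probe sets gave a smaller change for ALB, KNG1, CYP1A1 and FEN1 (log2 change 3.14, 2.56, -3.09 and -1.08). A further probe set gave a larger change for KNG1 and FEN1 (log2 change 4.15 and -1.96). Leaving out 1 array ended the call of the oxidative phosphorylation list (day 2 replicate 2 or day 15 replicate 3, adjusted p = 0.0648 and 0.0852), of the gluconeogenesis list (day 15 replicate 1, adjusted p = 0.0552) and of the Paneth cell list (day 2 replicate 3, any day 8 replicate or day 15 replicate 4, adjusted p between 0.0532 and 0.0760).

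Over the 3 times, 2893 of 8210 probe sets changed by limma's F test. Of the probe sets that were higher at day 15 than at day 2, a median of 62.8% of the log2 change had been reached by day 8, and 61.9% of it in those that were lower. In the steps from day 2 to day 8 and from day 8 to day 15, 212 probe sets rose in both and 208 fell in both, against 56.6 and 56.2 expected of independent lists. Another 105 rose and then fell, against 64.3 expected, and 31 fell and then rose, against 49.5. Both steps share the day 8 arrays, whose errors enter them with opposite sign. With the day 8 arrays split between the steps, so that none was shared, 22 to 43 probe sets rose and then fell (median 37, against 9.96 to 18.4 expected of independent lists) and 3 to 8 fell and then rose (median 5, against 8.86 to 17.2 expected). Across probe sets, the log2 changes of both steps correlated with r = 0.05, against -0.50 in simulated groups with no change and a mean of 0.18 with the arrays split. Their covariance exceeded the simulated one by 0.05.

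Genes that rose by day 8 and then fell by day 15 included PLA2G2A (1388 ± 430, 8678 ± 196 and 2004 ± 466 at the 3 times), CEACAM6 (2164 ± 437, 7922 ± 210 and 2020 ± 275), CEACAM5 (225 ± 54.7, 1746 ± 245 and 539 ± 128), ALB (278 ± 159, 9603 ± 722 and 4328 ± 1168) and TFF1 (1202 ± 257, 13457 ± 870 and 6632 ± 979). The collagenase MMP1 had 851 ± 206, 2273 ± 286 and 344 ± 93.6. PDGFRB had 261 ± 281, 1398 ± 328 and 187 ± 176, around the floor at day 2 and day 15. Without a floor neither of its steps passed (adjusted p = 0.179 and 0.226), nor its rise with the actin ratio as a covariate (adjusted p = 0.0930). With the actin ratio as a covariate 44 probe sets rose and then fell, 7 fell and then rose, 103 rose in both steps and 138 fell in both. The count that fell and then rose was 50 without day 8 replicate 2.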

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

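The tests of the TFRC ratio and of the split day 8 arrays were chosen after the results were seen, and the other scalings and left-out arrays were added for the genes highest at day 8 after the data were seen. In 544 groups of 4 arrays (187 named genes, each time taken apart where it could be tested), 22 held 1 array far from the other 3 by Dixon's criterion, against 27.2 expected by chance, and none of 27 groups of array measures did. At day 2, replicate 1 stood apart for AHSG (3155, the others from 3649 to 3737), CCN1 (879, the others from 1064 to 1076) and PKP4 (2496, the others from 2217 to 2259). Replicate 2 stood apart for JUND (16985, the others from 18335 to 18441), SLC3A2 (12445, the others from 15525 to 15830) and SPINK1 (9055, the others from 7937 to 8030). Replicate 3 did so for ABCC3 (951, the others from 588 to 648), and replicate 4 for CYP1A1 (6387, the others from 3828 to 4123) and RRP1B (3313, the others from 2740 to 2783). At day 8, replicate 2 stood apart for ENO1 (35733, the others from 45146 to 46269) and HIF1A (1215, the others from 602 to 656), and replicate 3 for DUSP5 (2025, the others from 2293 to 2308). At day 15, replicate 1 stood apart for ABCA1 (1327, the others from 49 to 264), KNG1 (3432, the others from 3766 to 3809) and SLC7A5 (1730, the others from 2098 to 2170). Replicate 3 stood apart for ACAT2 (1396, the others from 915 to 994), ADM (646, the others from 723 to 738), APOA1 (76018, the others from 61602 to 63447), TFF2 (1359, the others from 1148 to 1157) and TSPAN1 (2543, the others from 2151 to 2213), and replicate 4 for ESPL1 (2595, the others from 1764 to 1881) and IRF9 (734, the others from 567 to 587).

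The 3'/5' ratio of the actin control probe sets, which no comparison used, was 1.439 at day 8 and 1.591 at day 15 against 1.098 at day 2. RNA degradation that grows with culture time and acts on all transcripts alike is argued against, because the TFRC ratio at day 15 was 2.345 against 2.907 ± 0.548 at day 2 and the GAPDH ratio moved by less than its spread. The 5' probe set of TFRC was itself brighter at day 15 (1668 ± 133 against 750 ± 162 at day 2), so its ratio is a limited guide. Another control, ISGF3A, had 3' means of 3095, 2609 and 2957 and 5' means of 311, 205 and 330 at the 3 times. The noisier ratio of 18S was 2.004 ± 0.814 at day 2, 1.717 ± 0.992 at day 8 and 2.567 ± 0.448 at day 15. Saturation of the bright actin 3' probe set stays open. Within times its log2 value followed that of the 5' probe set with a slope of 1.303 ± 0.137, against 0.21 across times. The scaling of each array moves both values together, so the slope within times cannot decide. A change in actin transcripts with time, or a degradation that acts on some transcripts, may remain too, as hypotheses that were not tested. The ratio follows time, so a fit that holds both tells them apart only in part. In that fit 853 probe sets passed for day 8 against day 2, 744 for day 15 against day 8 and 946 for day 15 against day 2.

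Genes that were highest at day 8 rose and then fell in 105 probe sets. Chance error of the shared day 8 arrays is argued against as the whole cause, because with those arrays split between the steps a median of 37 did so, against 16.2 expected of independent lists. That expectation takes every tested probe set as equally likely to be called, so it is a rough guide. A single day 8 array out of line is argued against, because at least 71 did so without any 1 of the 4. The scaling of the arrays is argued against, because 87 or more did so under quantile or median scaling. A passing state of the cultures around day 8 may underlie these genes, as a hypothesis found and tested on the same arrays.

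Albumin, alpha-fetoprotein and other liver genes were higher at day 8 and day 15. A share of liver line cells that changed from day 8 to day 15 is argued against as the whole cause of that step, because of the liver list's members bright at both times 5 fell and 4 rose. For the rise by day 8, such cells cannot be told apart from a change in the cultured cells. Of 22 other hepatocyte genes 12 were bright enough to test, of which 3 rose (AGT, APOH and SERPINF2, named after their values were seen), and 8 of the 22 lay at or under the floor on all day 8 arrays. The bound set beforehand counted all 22, and by it the 3 that rose would have argued against such cells. Genes too dim to test decide nothing, so the bound was applied to the 12 tested instead, where it does not decide. Cross-hybridisation of 1 probe set alone is argued against for ALB, because 1 of 1 other tested probe sets rose too (log2 change 4.23, adjusted p = 3.75e-10). A relative that both probe sets bind stays open. So does cross-hybridisation for the 16 of 17 risen genes that have no other tested probe set and may be read by relatives.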

How the results depend on the processing

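The higher floor, the pseudocount, the inverse hyperbolic sine, the actin covariate and the fit without both arrays with dim spike-ins were chosen after seeing the data, as were all alternatives for the counts over both steps. The planned floor and pseudocount at the pooled 20th percentile (-31) could not be run, since values below 0 have no logarithm. Of 48 calls of lists, 31 held in all alternatives, and of 362 calls of named genes 233 did. In 27 settings, the requirement of a 2-fold change aside, the counts ran from 853 to 2256 for day 8 against day 2, from 710 to 987 for day 15 against day 8 and from 946 to 3241 for day 15 against day 2, with 1675 to 2057, 712 to 913 and 2553 to 3004 when 1 array was left out. The replicate block gave 2005, 922 and 2921, but whether the replicate numbers pair the arrays stays open. Of 12 same-number pairs 3 correlated above 0.1 (highest 0.21, and 0.15 among other numbers), and both arrays with dim spike-ins were replicate 2. The main fit left out 4348 probe sets as too dim to test, and with no filter on dim probe sets the counts were 1739, 760 and 2622.

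With the actin ratio as a covariate, 853 probe sets changed for day 8 against day 2 (2003 without it), 946 for day 15 against day 2 (2953) and 1240 by the F test (2893), 44 rose and then fell (105), 7 fell and then rose (31), 103 rose in both steps (212) and 138 fell in both (208). The ratio follows time, so this fit has less power by construction. Under it the mean log2 change of ribosomal protein genes for day 8 against day 2 was -0.1568, that of oxidative phosphorylation genes for day 15 against day 2 was 0.06763 with a camera test that pointed down, and the log2 changes were 0.06414 for PLS3 (day 8 against day 2) and, for day 15 against day 2, 0.6834 for ABCA1, 0.5149 for HIF1A, -0.205 for TGFBR1 and -0.1961 for CDKN1A. With a change of at least 2-fold required, 669, 226 and 1291 probe sets passed, fewer by construction. With only the 8 arrays of both times 18 fell and then rose, and without 1 array 24 to 50 did, the most without day 8 replicate 2, and the cause was not tested. Fry called 29, 24 and 34 lists, since it does not compare a list with other genes, and an estimated correlation left 5 for day 15 against day 8. The dimmer probe set of a gene reversed its direction for SRM (0.1901 for day 8 against day 2, 0.5696 for day 15 against day 2), MKI67 (0.1887 for day 15 against day 8, 0.1005 for day 15 against day 2) and PKM (0.6757 and 0.5262 in the same comparisons). For day 15 against day 2 it did so for ABCA1 (0.08758), BTG3 (0.8793), CCND3 (0.03604), ATP2A2 (0.03612), ISG15 (1.471), H2AZ2 (0.4728) and 3 probe sets of ACVR1B (-0.2544, -0.1569 and -0.5178), and the cause was not tested. None of the reversed changes passed, and a further probe set of ACVR1B gave 0.12 (adjusted p = 0.785).

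The 17 calls of lists that did not hold ended in 1 to 17 settings each, given with the adjusted p. For day 8 against day 2, the call ended without a filter on dim probe sets for brush border hydrolases (0.0882), transporters (0.0527), gluconeogenesis (0.0559) and antigen genes (0.0527), with the higher floor for transporters (0.0660), polyamine genes (0.0744) and antigen genes (0.0675), and with a filter on the mean for polyamine genes (0.0721) and gluconeogenesis (0.0692). Array weights ended it for gluconeogenesis (0.0526) and antigen genes (0.0623), the 8 arrays alone for gluconeogenesis (0.0590), and the fit without both arrays with dim spike-ins for antigen genes (0.0845). For day 15 against day 8, that fit ended the call of ribosome biogenesis (0.0578), fibroblast (0.0573) and proteasome genes (0.0573), the higher floor that of ribosome biogenesis (0.0793), mitosis (0.0788) and proteasome genes (0.0675), and the filter on the mean that of mitosis and proteasome genes (0.0721 each). Fibroblast genes also lost it with no floor (0.0745), no filter (0.0779), array weights (0.0526) and the actin covariate (0.0840), and proteasome genes with no floor (0.0501), the pseudocount (0.0506), the inverse hyperbolic sine (0.0513) and array weights (0.0657).

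For day 15 against day 2, no filter ended the call of brush border hydrolases (0.0716) and gluconeogenesis (0.0808), the filter on the mean that of gluconeogenesis (0.0538), and the fit without both arrays with dim spike-ins that of oxidative phosphorylation (0.0542). The Paneth cell list lost it in 17 settings, with adjusted p from 0.0532 to 0.114, among them the replicate block (0.0542), the 8 arrays alone (0.0681), no floor (0.0652), the higher floor (0.0675) and no filter (0.0864). Calls that ended without 1 array, with the actin covariate or with an estimated correlation are given with each comparison.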

Other observations

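The test of contractile genes at the end of this part was chosen after the results were seen. Most lists that were not called for day 15 against day 2 held members that moved both ways, the enteroendocrine and metallothionein lists apart. G1 cyclin and cell cycle inhibitor genes rose in 7 and fell in 4 of 24 tested members (7 and 4 adjusted over the list alone, camera adjusted p = 0.452). CCNG2, a cyclin of resting cells, rose 5.23-fold from 364 ± 59.1 to 1887 ± 17 and MXI1, an antagonist of MYC, 3.39-fold, a call that ended on 1 of its other probe sets (log2 change 0.56, adjusted p = 0.108). CCND1, CDK2, BTG3 and CCND3 fell by 1.77-, 1.56-, 1.85- and 1.45-fold, but the dimmer probe sets of BTG3 and CCND3 did not fall (log2 change 0.88 and 0.04, adjusted p = 0.0574 and 0.896). Glycolysis and hypoxia genes rose in 10 and fell in 8 of 31 (10 and 9 adjusted over the list alone, camera adjusted p = 0.796). NDRG1, a hypoxia-induced gene, rose 5.21-fold to 8202 ± 657. The glucose transporter SLC2A3 fell 3.67-fold from 52785 ± 3803 to 14357 ± 379, PFKP 5.72-fold, ADM 4.99-fold, PGAM1 1.72-fold, PKM 1.78-fold, ENO1 1.35-fold, TPI1 1.16-fold and HIF1A 2.04-fold. All 8 that fell are named because they went against the list's majority, while most of the 10 that rose are not. The dimmer probe set of PKM did not fall (log2 change 0.53, adjusted p = 0.224), nor did HIF1A with the actin ratio as a covariate (log2 change 0.51). Fatty acid oxidation genes rose in 9 and fell in 2 of 21 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0527), with ACADM up 2.94-fold and ACAA2 and ECHS1 down 1.99- and 1.44-fold. Cholesterol synthesis and uptake genes fell in 8 and rose in 4 of 19 (8 and 6 adjusted over the list alone, camera adjusted p = 0.402), with ACAT2 down 2.95-fold and INSIG1, SREBF1, SREBF2 and PMVK up 1.75-, 1.94-, 1.31- and 2.22-fold. Cell junction genes rose in 9 and fell in 5 of 26 (10 and 5 adjusted over the list alone, camera adjusted p = 0.647). CDH17, the cadherin of intestinal epithelium, rose 1.62-fold to 11549 ± 157 and the claudin CLDN3 2.86-fold. PKP2, VCL, PKP4, NECTIN2 and PPL fell by 3.06-, 1.82-, 1.72-, 1.37- and 1.23-fold. Leaving out 1 array ended the call of CCND3 (day 2 replicate 2, or day 15 replicate 1 or 2, adjusted p between 0.0599 and 0.0668). It did so for TPI1 (day 2 replicate 1 or 3, or day 15 replicate 1 or 2, adjusted p between 0.0574 and 0.0801). The call of HIF1A ended in 5 such fits (day 2 replicate 2, 3 or 4, or day 15 replicate 2 or 3, adjusted p between 0.0764 and 0.111) and that of PMVK in 9 (any day 2 array, day 8 replicate 1 or 2, or day 15 replicate 2, 3 or 4, adjusted p between 0.0510 and 0.113).

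Stress and signalling lists were mixed too. ER stress and amino acid response genes fell in 6 and rose in 3 of 21 tested members (6 and 3 adjusted over the list alone, camera adjusted p = 0.0893), with the amino acid transporter SLC7A5 down 5.71-fold from 11554 ± 1152 to 2025 ± 200 and HERPUD1, DDIT3 and CANX up 2.03-, 3.63- and 1.32-fold. The call of DDIT3 ended on its other probe set (log2 change 1.05, adjusted p = 0.0634). Immediate early genes fell in 6 and rose in 5 of 23 (6 and 5 adjusted over the list alone, camera adjusted p = 0.384), with IER3 down 4.00-fold and KLF10, ZFP36, JUND, FOSB and FOSL2 up 3.13-, 2.34-, 1.32-, 2.89- and 1.44-fold. Wnt targets and crypt genes fell in 6 and rose in 3 of 22 (6 and 3 adjusted over the list alone, mean log2 change -0.25, median 0.01, camera adjusted p = 0.453), with ID1 down 8.64-fold, ID2 up 2.38-fold, TCF7L2 up at least 4.31-fold and CD24 up 1.43-fold. TGF-beta, BMP and EMT genes fell in 6 and rose in 3 of 23 (7 and 3 adjusted over the list alone, mean log2 change -0.28, median 0.06, camera adjusted p = 0.224), with BMP2 down 4.29-fold and ACVR1B, TGFBR1 and THBS1 up 1.53-, 2.09- and 2.5-fold. But 3 other probe sets of ACVR1B pointed down without passing (log2 change -0.25, -0.16 and -0.52, adjusted p = 0.564, 0.782 and 0.459). A further one gave 0.12 (adjusted p = 0.785). TGFBR1 with the actin covariate also pointed down (-0.21). Antigen presentation and interferon genes rose in 7 and fell in 1 of 24 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0699), with B2M up 1.79-fold and ISG15 down 1.36-fold, though not on its dimmer probe set (log2 change 1.47, adjusted p = 0.0520). Histone genes, uncertain among near-identical relatives, rose in 8 and fell in 3 of 17 (8 and 3 adjusted over the list alone, camera adjusted p = 0.466), with H2AX, H2AZ2 and H2AZ1 down 2.65-, 2.04- and 2.23-fold, H2AZ2 not on its dimmer probe set (log2 change 0.47, adjusted p = 0.0601). These 3 histone genes are named because they went against the list's majority. Vitamin D and calcium transport genes rose in 2 and fell in 1 of 11 (camera adjusted p = 0.647), with RXRA up 2.05-fold and ATP2A2 down 1.56-fold, though not on its dimmer probe set (log2 change 0.04, adjusted p = 0.869). Fibroblast and matrix genes rose in 2 and fell in 2 of 15 (mean log2 change -0.22, median 0.14, camera adjusted p = 0.839), immune cell genes rose in 2 and fell in 2 of 14 (camera adjusted p = 0.625), and enteroendocrine genes rose in 1 of 8 (camera adjusted p = 0.402). Metallothionein and zinc genes rose in 1 of 10 (camera adjusted p = 0.425), and housekeeping reference genes rose in 3 and fell in 3 of 13 (camera adjusted p = 0.646), with GUSB up 2.42-fold and TUBB down 2.07-fold. The cell junction, glycolysis and housekeeping lists had mean log2 changes of 0.10, 0.09 and 0.14, and the median of all probe sets was 0.10. Leaving out 1 array ended the calls of CD24 (day 15 replicate 1, adjusted p = 0.0548) and FOSB (day 2 replicate 3 or day 15 replicate 3, adjusted p = 0.0590 and 0.0596). It did so for THBS1 (day 2 replicate 1 or 2, adjusted p = 0.0509 and 0.0539). The call of FOSL2 ended in 6 such fits (day 2 replicate 1, 2 or 3, or day 15 replicate 1, 2 or 4, adjusted p between 0.0519 and 0.0973). That of ISG15 did in 6 (day 2 replicate 1, 3 or 4, or day 15 replicate 1, 2 or 3, adjusted p between 0.0508 and 0.113). Median scaling ended those of CD24, JUND and FOSL2 (adjusted p = 0.0858, 0.0692 and 0.124). The higher floor ended those of TCF7L2 and THBS1 (adjusted p = 0.165 and 0.133). Another probe set ended those of JUND and RXRA (adjusted p = 0.196 and 0.0880), while a further one of JUND rose and passed (log2 change 0.365, adjusted p = 0.00299).

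Chance is argued against for each count of probe sets in the comparisons, since no other split came near it. For the lists the real split also gave the most, but 1 of 35 is the smallest share that these splits can give. Other splits called up to 18 lists, so the splits do not exclude chance for the list counts. In 35 splits of the 8 arrays of day 8 and day 2 into 4 and 4, only 1, the real one, gave as many probe sets (2003, highest other 3) or lists (19, highest other 18). For day 15 against day 8 it was 1 of 35 for probe sets (929, highest other 3) and 1 of 35 for lists (11, highest other 7), and for day 15 against day 2 it was 1 of 35 for probe sets (2953, highest other 2) and 1 of 35 for lists (18, highest other 16). In 100 splits of the 12 arrays into 3 groups of 4, 1 gave as many probe sets by limma's F test (2893, highest other 967), 1 as many that rose in both steps (212, highest other 0) and 1 as many that fell in both (208, highest other 0). The count that rose and then fell was reached in 3 of 100 splits (105, highest other 209) and the count that fell and then rose in 3 of 100 (31, highest other 236). Both larger splits put all 4 day 15 arrays in the middle group, so they follow the structure of the time course. Most splits mix the times, so they test for any difference between times and not for a change of direction. They therefore decide nothing about these counts, and the count that fell and then rose was below the 49.5 expected of independent lists.

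A hypothesis from the falls of TAGLN, CNN3, VCL and CCN1 was that contractile and actin-binding genes fell more widely. A list of 29 other such genes, written before their values were looked at, had 27 tested members, of which 17 fell and 1, MYO1E, rose from day 2 to day 15 (camera p = 7.82e-07, p = 0.0027 with an estimated correlation). ZYX, the focal adhesion protein zyxin, fell from 7329 ± 472 to 1067 ± 291 and the actin-binding protein TAGLN2 from 19301 ± 1223 to 7119 ± 827. By day 8, 12 of the 27 had fallen and 2 had risen, and 6 fell from day 8 to day 15. A wider fall of contractile genes may thus accompany the culture time, as a hypothesis found and tested on the same arrays. This list was not tested with the actin ratio, which rose over the same times, as a covariate, nor with the other processing alternatives.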
